A study of Mus musculus with 29 samples.

How the data were processed

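Gene expression was measured by mRNA sequencing in NMM, a mouse melanoma cell line with mutant NRAS. The cells received a first stimulation with medium, interferon gamma (IFNγ, 100 ng/ml) or transforming growth factor beta (TGFβ, 10 ng/ml) for 2, 6, 12 or 24 h. They were then washed 5 times with PBS and given a second stimulation of 24 h with medium, IFNγ, TGFβ or, in 1 library, a mix of both cytokines. Per the labels' protocols, the cells grew in IMDM with 10% fetal calf serum, total RNA was isolated on columns with DNase digestion, samples with an RNA integrity number over 8 went into a stranded mRNA library kit, and the pooled libraries were sequenced on an Illumina NovaSeq.

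The authors deposited 1 table of whole-number read counts per Ensembl gene for 29 libraries, with no normalisation. HISAT, without a version, and the genome build GRCm38 are named in the submitters' processing notes. The counting tool, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene might not be separated, and genes of near-identical families (Gbp, Ifit, H2, Ly6, Slfn) are uncertain where the counting could split or drop shared reads. The table held 28229 genes, each with at least 1 read in some library. Of their identifiers 28182 were in GENCODE release M21 and 27962 had the same coordinates there. Coordinates are those of the deposited table, on GRCm38. Every column of the table was matched to 1 sample by its name, and 0 columns were left over.

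Library totals ran from 17179530 to 23668015 counts, and the share of mitochondrially encoded transcripts from 0.596% to 1.31%. Intervals and count floors cover counting error only. No 2 libraries of 1 group held counts that agreed within sampling noise, since the lowest chi-square per degree of freedom between libraries of 1 group was 3.96.

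Libraries were grouped by the sequence of stimuli in their labels. This gave 7 groups of 4 libraries, 1 per duration of the first stimulation, and 1 library that received medium and then the mix. The labels name no further replicates, so the 4 durations stand as the replicates of a sequence. No label says that libraries came from separate experiments, and p-values therefore measure the spread between these samples, which may be technical in part. The replicate numbers are the durations, and duration was a factor in the main model. Deviations from the group means correlated between libraries of the same duration by 0.233 to 0.586 for TGFβ before IFNγ, by 0.339 to 0.663 for IFNγ before TGFβ, by 0.186 to 0.654 for the order of the cytokines, by 0.168 to 0.475 for IFNγ first against second and by 0.632 to 0.83 for TGFβ first against second. In the comparisons with medium alone the correlations ran from -0.0791 to 0.424, so the data alone leave open whether the duration pairs these libraries. For IFNγ second they were -0.0791, 0.424, 0.178 and 0.35 at 2, 6, 12 and 24 h. Those for TGFβ second were 0.117, 0.245, 0.093 and 0.215.

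Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group at a minimum count of 10, which left 14935 genes, and libraries were scaled with TMM factors. A quasi-likelihood negative binomial model (glmQLFit, glmQLFTest) with a term per group and a factor for duration was fitted to all 29 libraries, with 18 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 14935 genes from this edgeR test, and a gene was called at an adjusted p below 0.05. There were 7 contrasts between groups and 2 interaction contrasts. Trends with duration came from a model with an intercept and a slope on log2 duration per group, with 14 residual degrees of freedom. Log2 fold changes carry standard errors (SE), taken as the fold change over the root of the F statistic. Values per library are CPM, the counts relative to TMM-scaled library sizes, and log2 CPM used a prior count of 2.

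The design, the alternatives, the rule for named genes and 25 gene lists were fixed before the data were examined. Lists covered the IFNγ response, GTPases, antigen presentation, chemokines, T cell inhibitory ligands, antiviral genes, cell death, TGFβ signalling and targets, extracellular matrix, epithelial-mesenchymal transition, melanocyte and undifferentiated states, cell cycle, MAPK output, NF-kB targets, metabolism and stress, p53 targets, reference genes and markers of leukocytes, fibroblasts and endothelium. Of these, 23 had at least 5 tested members and were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 161 tests (23 lists in 7 comparisons). List tests for the interactions were adjusted as a family of their own together with 2 contrasts added later. camera with an estimated correlation and fry were alternatives. camera with the preset called 78 of the 161 tests, camera with an estimated correlation 0, and fry 73. fry asks whether the members of a list move on balance in 1 direction and does not compare a list with other genes.

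Named genes are 20 genes chosen for their part in the 2 cytokine responses. To these come, per comparison, the 5 highest and 5 lowest log2 fold changes among called genes with at least 5 CPM on average, a symbol that is not a clone name and the same sign at all 4 durations, and up to 4 members of each list with the smallest p. Names outside this rule are marked as chosen after their values were seen. Results of some single genes that this rule names are not reported here.

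The retained share of a response was computed per duration, as the log2 difference after the first cytokine and 24 h in medium divided by the log2 difference after 24 h of that cytokine as second stimulus. It is given as a median over called genes with an absolute log2 fold change of at least 1. Overlaps of comparisons that share the 4 medium libraries were set beside the overlap of independent lists and beside fits with these split between both. They were also set beside 12 simulations of unchanged groups, with the medium libraries redrawn from their fitted mean. The mix library has no replicate and no test. Its values were set beside the sum of the log2 differences of both single cytokines at 24 h.

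Each test was run first on simulated counts drawn from the means, dispersions and totals of the real libraries for the 14935 genes, with 200 genes changed by known folds. At 1.5, 2 and 4-fold, edgeR recovered 59.7%, 76.1% and 93.9% of changed genes for IFNγ second with 7 false calls, 67.2%, 80.6% and 93.9% for TGFβ second, 59.7%, 73.1% and 93.9% for IFNγ first, and 61.2%, 73.1% and 83.3% for TGFβ first, these 3 with 6, 4 and 3 false calls. At the same folds it recovered 68.7%, 85.1% and 87.9% for TGFβ before IFNγ, 58.2%, 73.1% and 90.9% for IFNγ before TGFβ, and 53.7%, 85.1% and 93.9% for the order of the cytokines, with 12, 10 and 7 false calls. For the interactions it recovered 37.3%, 61.2% and 83.3% (TGFβ before IFNγ) and 50.7%, 68.7% and 78.8% (IFNγ before TGFβ), with 4 and 5 false calls. For trends of 1.25, 1.5 and 2-fold per doubling of the duration it recovered 25.4%, 70.1% and 69.7% (IFNγ then medium), 40.3%, 61.2% and 78.8% (TGFβ then medium), 34.3%, 55.2% and 80.3% (TGFβ then IFNγ), and 19.4%, 59.7% and 74.2% (IFNγ then TGFβ), with 4, 12, 2 and 4 false calls. In the design of IFNγ second, each of the 3 list tests called 20 of 20 simulated lists shifted by 1.5-fold and 0 of 200 unshifted lists. Genes were drawn independently there, so the rate of false calls for lists whose genes move together was not tested. A first version with 4 unshifted lists had 1 of them called, and the number of lists was then raised to 200 with the same seed.

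The alternatives were RLE size factors, library sizes without mitochondrially encoded genes, no low-count filter, DESeq2 1.42.0, no duration factor, only the groups compared, duration in hours for trends, a prior count of 0.5 and another medium reference for the retained share, a fold change threshold of 2 on the log2 scale for its genes, group means in place of the 24 h libraries for the mix, and leaving out each library and each duration in turn. Chosen after the data were seen were list tests without the 6 h medium library, the retained share against the 2, 12 and 24 h medium libraries, a fit of all comparisons without the 6 h medium library, the exchange of whole sequences, and 2 contrasts of the same cytokine as first against second stimulus.

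To judge chance, each comparison was repeated over all 35 splits of its 8 libraries into equal groups, or over 100 drawn splits for the interactions, the real one included. Durations of 12 and 24 h were set against 2 and 6 h for 3 lists as the mean over members and sequences. The sequences with and without TGFβ were compared by an exact two-sided test over 35 exchanges of whole sequences, with Benjamini-Hochberg adjustment over the 3 lists, and the durations by 6 arrangements taken jointly in all sequences. Libraries far from the other 3 of their sequence were marked by Dixon's ratio at a level of 5%.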

Results

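Transcript levels of the NRAS-mutant mouse melanoma line NMM were measured in 29 mRNA libraries after a sequence of 2 stimuli, to follow how the T cell cytokines IFNγ and TGFβ act on tumour cells over time. A first stimulation of 2, 6, 12 or 24 h was washed away and followed by 24 h of a second one. There were 7 sequences with 4 libraries each, 1 per duration of the first stimulation: medium then medium, medium then IFNγ, medium then TGFβ, IFNγ then medium, TGFβ then medium, TGFβ then IFNγ, and IFNγ then TGFβ. Medium followed by a mix of both cytokines was measured in 1 library. Library totals lay between 17179530 and 23668015 counts, and 14935 genes were tested. Values are mean CPM ± SD over the 4 libraries of a sequence, and changes are log2 fold changes.

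The first and second principal components held 38.9% and 18.3% of the variance. On the first, the libraries that ended with IFNγ and the mix lay apart from the others, while sequences such as medium and IFNγ then medium overlapped on both. Of the 4 medium libraries, that of 6 h stood apart. Its log2 levels differed from the mean of the other 3 by an SD of 0.467 over genes, against 0.165 to 0.212 for the others. Its mitochondrial share was 1.24%. Igfbp5, an IGF-binding protein, lay at 4060 CPM there against 493 on average in the other 3. Slfn4, of the interferon-inducible Schlafen family, lay at 0.462 against 7.45. Leukocyte markers were near the floor in all libraries (Ptprc, the pan-leukocyte antigen CD45, reached at most 0.167 CPM), apart from Cd14 with up to 77 CPM and Cd68 with up to 6.32 CPM. With 2 tested members that list was too short for a test. Gene counts of the 7 comparisons are therefore also given without the 6 h medium library. Of 161 list tests, 62 had a number of risen or fallen members that moved at least 1.5 times without it, and the result of 9 tests changed sides. List results without it are given for some of these.

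IFNγ given for 24 h as second stimulus raised the T cell attracting chemokine Cxcl9 (chromosome 5, 92321347 to 92328079) from 0.185 ± 0.144 to 131 ± 17.7 CPM (SD, n = 4), a log2 fold change of 9.42 (SE 0.444, adjusted p = 4.54e-13). Cd274 (chromosome 19, 29367455 to 29388095), which encodes the T cell inhibitory ligand PD-L1, rose from 20.2 ± 6.48 to 271 ± 16.9 CPM (SD, n = 4), by 3.70 (SE 0.419, adjusted p = 3.51e-07). The transcription factor Irf1 (chromosome 11, 53770014 to 53778374) rose by 3.73 (SE 0.278) and the signalling inhibitor Socs1 by 2.21 (SE 0.157). The MHC class I heavy chain H2-K1 (chromosome 17, 33996017 to 34000347) rose from 651 ± 20.2 to 1443 ± 210 CPM (SD, n = 4), by 1.10 (adjusted p = 0.00623).

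Among the genes with the highest fold changes were the apolipoprotein L gene Apol6 (8.21), the transcription factor Batf2 (8.11), the GTPase Gbp4 (6.55) and Acod1, the enzyme that makes itaconate (5.32). The lowest were Prg4, which encodes lubricin (-5.78), Igfbp5 (-3.80), the engulfment receptor Megf10 (-3.26), carboxypeptidase M, Cpm (-3.06), and the phosphodiesterase Pde3a (-2.75). All 10 went the same way at all 4 durations. The 6 h medium library carries part of the low values: without it they were -3.86 for Prg4, -2.77 for Igfbp5, -2.81 for Megf10, -2.44 for Cpm and -2.24 for Pde3a.

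Of the 17 tested GTPases of the GBP and IRG families, 16 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 2.49, among them Gbp2 by 3.74 and Tgtp1 by 4.15 (camera adjusted p = 3.43e-06, and adjusted p = 0.466 with an estimated correlation). Of 22 genes of MHC class I antigen presentation, 16 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 2.53e-05, and adjusted p = 0.516 with an estimated correlation). Among them were the peptide transporter subunits Tap1 (1.37) and Tap2 (1.98) and the immunoproteasome subunit Psmb10 (1.72). B2m, the MHC class I light chain, had 0.26 and did not pass. Chemokines rose in 8 of 11 cases and fell in 0 (8 and 0 adjusted over the list alone), with Ccl2 at 3.45 and Cxcl10 at 2.76 (camera adjusted p = 0.000114, and adjusted p = 0.201 with an estimated correlation). IFNγ signalling genes rose in 10 and fell in 2 of 17 cases (10 and 2 adjusted over the list alone), led by Irf8 at 2.35 (camera adjusted p = 3.55e-05, and adjusted p = 0.32 with an estimated correlation). Only 3 of 12 MHC class II genes passed the count filter, and their activator Ciita was close to the floor. Antiviral genes of the type I interferon kind rose in 8 and fell in 1 of 30 cases (3 and 1 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.0825). Without the 6 h medium library 2 of them rose. The call of Tap1 was lost without the 6 h medium library (adjusted p = 0.0678).

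Cell cycle genes were higher with IFNγ: 32 of 38 rose and 0 fell (34 and 0 adjusted over the list alone), with cyclin E1, Ccne1, at 2.03 and the topoisomerase Top2a at 0.85 (camera adjusted p = 1.03e-08, and adjusted p = 0.483 with an estimated correlation). Of the list, 29 rose and 2 fell without the 6 h medium library. Extracellular matrix genes were lower, with 4 that rose and 21 that fell of 35 (4 and 22 adjusted over the list alone; camera adjusted p = 9.48e-05, and adjusted p = 0.39 with an estimated correlation). The type III collagen gene Col3a1 fell from 742 ± 480 to 168 ± 27.7 CPM (SD, n = 4). The proteoglycan Dcn fell by 2.14 on the log2 scale, while the proteoglycan Vcan rose by 1.33. The 6 h medium library had 461 CPM of Dcn against 88.8 on average in the other 3, and without it the log2 fold change of Dcn was -1.54, and the calls of Col3a1 and Vcan held. Col3a1 and Dcn are also on the list of fibroblast and endothelium markers, of which 5 fell and 0 rose of 6 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0114, and adjusted p = 0.201 with an estimated correlation). The median of these markers was -1.32, and -1.16 without the 6 h medium library. Cell death genes rose in 15 and fell in 1 of 20 cases (15 and 1 adjusted over the list alone), with the inflammatory caspase Casp4 at 2.47 (camera adjusted p = 9.63e-06, and adjusted p = 0.215 with an estimated correlation). NF-kB targets rose in 14 and fell in 1 of 18 cases (15 and 1 adjusted over the list alone; camera adjusted p = 3.11e-05, and adjusted p = 0.32 with an estimated correlation). TGFβ targets rose in 9 and fell in 8 of 22 cases (9 and 9 adjusted over the list alone; camera adjusted p = 0.943). Without the 6 h medium library 5 of them fell.

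The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 6547 genes for IFNγ as second stimulus, of which 3388 were higher and 3159 lower. It called 5834 without the 6 h medium library. The lists above hold families with shared reads (Gbp, H2), for which single members are uncertain. No libraries are labelled as replicates, so the durations stand in for them. The p-values measure the spread left after the terms for sequence and duration, pooled over all sequences.

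**Figure D1:**
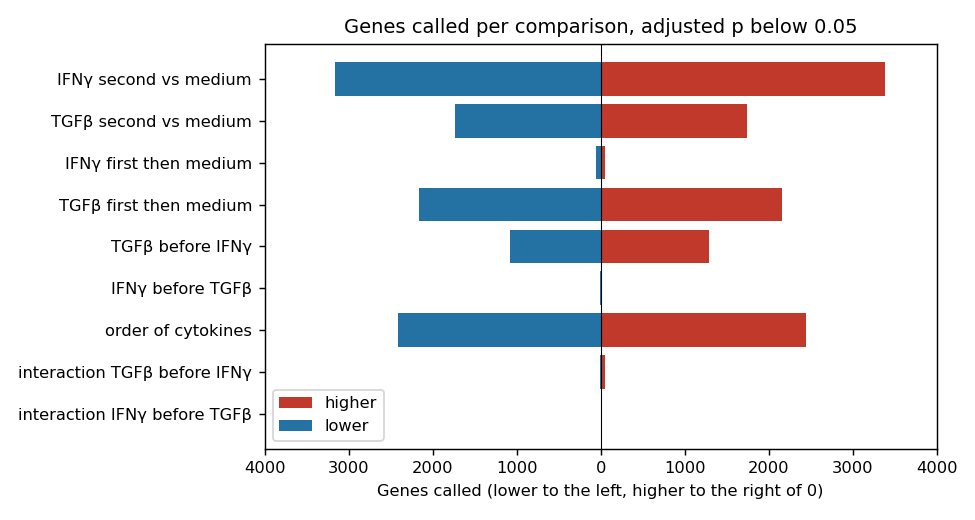
Number of genes called higher and lower (horizontal axis, genes at an adjusted p below 0.05) in each of 7 comparisons and 2 interactions. IFNγ as second stimulus gave 6547 calls and IFNγ as first stimulus 118, while TGFβ gave 3477 and 4326.

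TGFβ given for 24 h as second stimulus raised the feedback inhibitor Smad7 (chromosome 18, 75367529 to 75395935) from 39.2 ± 1.84 to 60.3 ± 10.9 CPM (SD, n = 4), by 0.61 (SE 0.114, adjusted p = 0.000468). The matrix protein Tgfbi rose by 0.83 (SE 0.185). The macrophage elastase Mmp12 rose from 2.21 ± 1.72 to 20.8 ± 1.6 CPM (SD, n = 4), by 3.28 (SE 0.32, adjusted p = 2.34e-07). The matrix glycoprotein Fbln2 rose by 2.42 (SE 0.193). In the same cells Cd274 fell from 20.2 ± 6.48 to 7.6 ± 4.31 CPM (SD, n = 4), by 1.62 on the log2 scale (adjusted p = 0.0112). H2-K1 fell from 651 ± 20.2 to 328 ± 211 CPM (SD, n = 4; adjusted p = 0.00654).

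Other high fold changes were those of Ggct, an enzyme of glutathione turnover (2.34), and the collagen-binding integrin Itga2 (2.08). The lowest were Prg4 (-3.42), the extracellular superoxide dismutase Sod3 (-3.35), the water channel Aqp5 (-3.11), the surface protein Ly6a (-3.09) and the lipid carrier Apod (-2.97). With the 6 h medium library left out, Prg4 had -1.60, Sod3 -2.30, Aqp5 -2.21, Ly6a -3.37, Apod -3.20, Ggct 2.09 and Itga2 1.76.

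Antiviral genes fell in 17 and rose in 0 of 30 cases (29 and 0 adjusted over the list alone), with a median of -1.44. The 2'-5'-oligoadenylate synthetase Oas2 fell from 117 ± 23.7 to 29.1 ± 26.2 CPM (SD, n = 4). The camera test gave adjusted p = 2.14e-07 for them, and adjusted p = 0.527 with an estimated correlation. GBP and IRG GTPases fell in 13 and rose in 0 of 17 cases (17 and 0 adjusted over the list alone; camera adjusted p = 3.06e-06, and adjusted p = 0.466 with an estimated correlation), with Gbp2 at -1.81. MHC class I genes fell in 19 and rose in 0 of 22 cases (22 and 0 adjusted over the list alone), with B2m at -0.93 and Tap1 at -1.38 (camera adjusted p = 5.95e-09, and adjusted p = 0.397 with an estimated correlation). Antiviral genes lay lower at 12 and 24 h than at 2 and 6 h here, by a mean log2 difference of -1.96. GTPases did so by -1.98 and MHC class I genes by -1.61, so these falls came mainly from the 12 and 24 h libraries. Cell death genes fell in 12 and rose in 0 of 20 cases (13 and 0 adjusted over the list alone; camera adjusted p = 9.63e-06, and adjusted p = 0.215 with an estimated correlation). p53 targets fell in 9 and rose in 0 of 20 cases (12 and 0 adjusted over the list alone), with the kinase Plk2 at -1.20 (camera adjusted p = 1.28e-05, and adjusted p = 0.201 with an estimated correlation).

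TGFβ targets rose in 10 and fell in 3 of 22 cases (10 and 4 adjusted over the list alone), with Ctla2a at 3.50 and the matricellular protein Ccn2 at 2.19, at 2.76 ± 1.36 CPM with TGFβ (SD, n = 4; camera adjusted p = 0.0249, and adjusted p = 0.32 with an estimated correlation). The TGFβ pathway inhibitor Skil had 0.06 and did not pass (adjusted p = 0.435). TGFβ signalling genes rose in 3 and fell in 6 of 21 cases (4 and 7 adjusted over the list alone; camera adjusted p = 0.563), with a median of 0.0127 and a mean of -0.0935. Without the 6 h medium library 5 rose. Genes of epithelial-mesenchymal transition and the cytoskeleton rose in 12 and fell in 4 of 22 cases (15 and 4 adjusted over the list alone), with the integrins Itgb3 at 1.02 and Itgb1 at 0.72 (camera adjusted p = 3.57e-05, and adjusted p = 0.201 with an estimated correlation). Of these genes, 1 fell without the 6 h medium library. Extracellular matrix genes rose in 5 and fell in 6 of 35 cases (5 and 6 adjusted over the list alone; camera adjusted p = 0.0799). Without that library 3 fell. Of 8 melanocyte genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.731), with Gpnmb at -1.47 and Mitf, the master transcription factor of melanocytes, at -0.41. Cell cycle genes rose in 11 and fell in 0 of 38 cases (14 and 0 adjusted over the list alone; camera adjusted p = 3.06e-06, and adjusted p = 0.573 with an estimated correlation), but in 3 without the 6 h medium library.

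The edgeR test with Benjamini-Hochberg adjustment called 3477 genes for TGFβ as second stimulus, 1741 higher and 1736 lower. It called 3143 without the 6 h medium library. The count was 1848 without all 12 h libraries, 2189 without all 24 h libraries, 1727 with no duration factor and 1047 in a fit of only these groups.

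**Figure D2:**
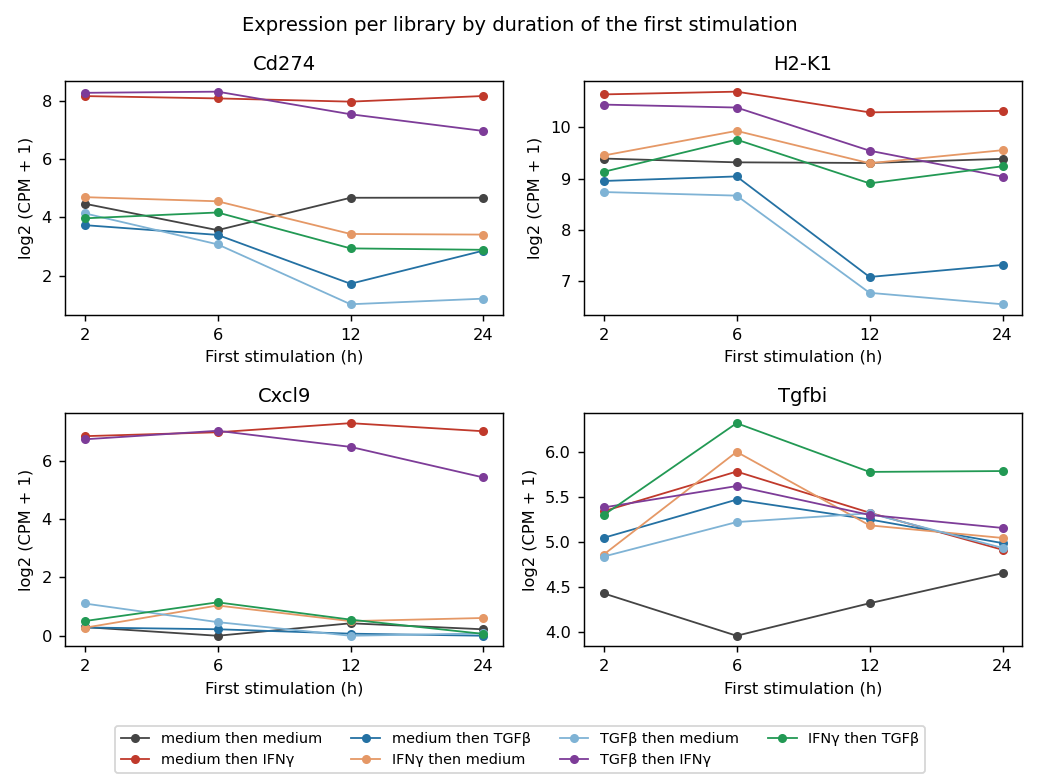
Level of 4 genes in each library (vertical axis, log2 of CPM + 1) against the duration of the first stimulation (horizontal axis, h) in 7 sequences of stimuli. Cd274 and Cxcl9 were high in the sequences that ended with IFNγ. H2-K1 was lowest in the sequences with TGFβ and no IFNγ.

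Cells that received IFNγ first and were then kept in medium for 24 h tested whether an IFNγ response outlasts the stimulus. The IFNγ-induced genes were near the level of medium cells: Cd274 lay at 16.7 ± 8.1 CPM against 20.2 ± 6.48 CPM (SD, n = 4; log2 fold change -0.49, adjusted p = 0.612). Irf1 had a log2 fold change of 0.01 (adjusted p = 0.987), Gbp2 of -0.45 (adjusted p = 0.764) and H2-K1 of 0.18 (adjusted p = 0.816). A smaller set changed. The integrin Itgb7 rose from 9.87 ± 1.23 to 24.1 ± 7.85 CPM (SD, n = 4), by 1.29 (SE 0.29, adjusted p = 0.0388), against 77.8 ± 8.36 CPM with IFNγ as second stimulus. The hypoxia-inducible mitophagy receptor Bnip3 rose from 62.5 ± 8.97 to 117 ± 26.7 CPM (SD, n = 4; adjusted p = 0.0172). Atf5, a transcription factor of the stress response, fell from 123 ± 23.3 to 67.8 ± 11.7 CPM (SD, n = 4), by 0.88 on the log2 scale (adjusted p = 0.00062). The other genes with the highest changes were mt-Nd3 (1.06), Tgfbi (0.94) and Syt7 (0.70). Those with the lowest were Igfbp7 (-0.99), Rflnb (-0.97), Penk (-0.95) and Serpinf1 (-0.86). With the 6 h medium library left out, Itgb7 (adjusted p = 0.0855), Syt7 (0.0659) and Rflnb (0.0937) did not pass the edgeR test.

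Glycolysis and hypoxia genes rose in 10 and fell in 0 of 28 cases (22 and 1 adjusted over the list alone), with the enzymes Pgam1 at 0.48, Ldha at 0.41 and Pkm at 0.30 (camera adjusted p = 1.09e-15, and adjusted p = 0.201 with an estimated correlation). Of that list, 4 rose without the 6 h medium library, and Ldha did not pass (adjusted p = 0.0557). Of 17 GBP and IRG GTPases, 22 MHC class I genes, 17 IFNγ signalling genes and 11 chemokines, 0 were called by edgeR, over all genes and adjusted over the list alone (camera adjusted p = 0.725 for the GTPases and 0.911 for MHC class I). Antiviral genes had 0 calls (0 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 0.00887, and adjusted p = 0.727 with an estimated correlation). Cell cycle genes had 0 calls with a median of 0.238 (0 adjusted over the list alone; camera adjusted p = 3.5e-09, and adjusted p = 0.477 with an estimated correlation). This list no longer passed without the 6 h medium library (adjusted p = 0.107). The same holds for TGFβ signalling genes with 0 calls (0 adjusted over the list alone), from adjusted p = 0.0252 (adjusted p = 0.457 with an estimated correlation) to 0.635. p53 targets had 0 calls (0 that rose and 4 that fell adjusted over the list alone; camera adjusted p = 1.71e-05, and adjusted p = 0.201 with an estimated correlation).

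The edgeR test with Benjamini-Hochberg adjustment called 118 genes for IFNγ as first stimulus, 57 higher and 61 lower, with 2356 at an unadjusted p below 0.05. DESeq2 called 403, which held 114 of the 118. The count was 64 without the 6 h, 498 without the 2 h and 23 without the 12 h medium library. It was 1, 9 and 41 without the IFNγ library of 6, 12 and 24 h. Further counts were 1, 0 and 43 without all libraries of 6, 12 and 24 h, 6 with no duration factor and 0 in a fit of only these groups.

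Cells that received TGFβ first and were then kept in medium for 24 h tested the same for TGFβ. Genes of the TGFβ response differed from medium here. Mmp12 lay at 27 ± 2.14 CPM (SD, n = 4), higher by 3.67 (SE 0.318, adjusted p = 3.48e-08), and Fbln2 was higher by 2.87 (SE 0.196). Smad7 rose by 0.32 (SE 0.114, adjusted p = 0.0402), higher in 3 of 4 durations. Cd274 fell from 20.2 ± 6.48 to 6.59 ± 7.3 CPM (SD, n = 4), by 1.90 on the log2 scale (SE 0.459, adjusted p = 0.00316). Its level after TGFβ and medium ranged from 1.03 to 16.6 CPM between libraries. H2-K1 fell by 1.60 on the log2 scale (SE 0.321). Other high changes were those of Itga2 (2.45) and Ggct (2.43). The lowest were Prg4 (-4.15), Apod (-4.11), Sod3 (-3.84), Ly6a (-3.84) and the perforin-like Mpeg1 (-3.40). The fit that leaves out the 6 h medium library gave Prg4 -2.26, Apod -4.35, Sod3 -2.81, Ly6a -4.12 and Mpeg1 -3.77.

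All 30 antiviral genes fell (30 and 0 adjusted over the list alone), with a median of -2.08, Oas2 at -3.06 and Ifit1 at -2.18 (camera adjusted p = 9.31e-14, and adjusted p = 0.397 with an estimated correlation). GBP and IRG GTPases fell in 16 and rose in 0 of 17 cases (17 and 0 adjusted over the list alone; camera adjusted p = 4.69e-09, and adjusted p = 0.39 with an estimated correlation). MHC class I genes fell in 21 and rose in 0 of 22 (22 and 0 adjusted over the list alone; camera adjusted p = 1.15e-11, and adjusted p = 0.353 with an estimated correlation). IFNγ signalling genes fell in 10 and rose in 0 of 17 cases (10 and 1 adjusted over the list alone; camera adjusted p = 0.000983, and adjusted p = 0.397 with an estimated correlation). Genes of epithelial-mesenchymal transition and the cytoskeleton rose in 14 and fell in 3 of 22 cases (15 and 3 adjusted over the list alone), with Itgb3 at 1.11 (camera adjusted p = 0.000132, and adjusted p = 0.201 with an estimated correlation). TGFβ targets rose in 8 and fell in 4 of 22 cases (9 and 4 adjusted over the list alone; camera adjusted p = 0.163). The list passed without the 6 h medium library (adjusted p = 0.0303). Cell cycle genes rose in 13 and fell in 0 of 38 cases (17 and 0 adjusted over the list alone; camera adjusted p = 2.21e-05, and adjusted p = 0.607 with an estimated correlation), and in 5 without that library.

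The edgeR test with Benjamini-Hochberg adjustment called 4326 genes for TGFβ as first stimulus, 2164 higher and 2162 lower. It called 3986 without the 6 h medium library. The count was 2690 without all 12 h libraries, 2615 with no duration factor and 1381 in a fit of only these groups.

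The share of a response still present 24 h after the washes was taken per duration. Of the IFNγ response, over 1256 genes, the median share was 4.85% after 2 h, 43.1% after 6 h (quartiles 17.7% and 63.3%), -3.92% after 12 h and -1.49% after 24 h. With the mean of the 2, 12 and 24 h medium libraries as reference, chosen after the 6 h medium library was seen to stand apart, the share after 6 h was 10.4%. Of the TGFβ response, over 646 genes, the median share was 100% after 2 h, 99.4% after 6 h, 110% after 12 h and 128% after 24 h (quartiles 98.8% and 170%). Libraries of TGFβ first and TGFβ second deviated together at the same duration, with correlations of 0.632 to 0.83. The share at a duration therefore does not separate the first stimulation from a deviation that both libraries of that duration share. Of the 583 genes raised at least 2-fold by IFNγ as second stimulus, 5 were called in the same direction after the washes, and of the 673 lowered ones 12. For TGFβ these numbers were 146 of 174 raised genes and 429 of 472 lowered ones.

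**Figure D3:**
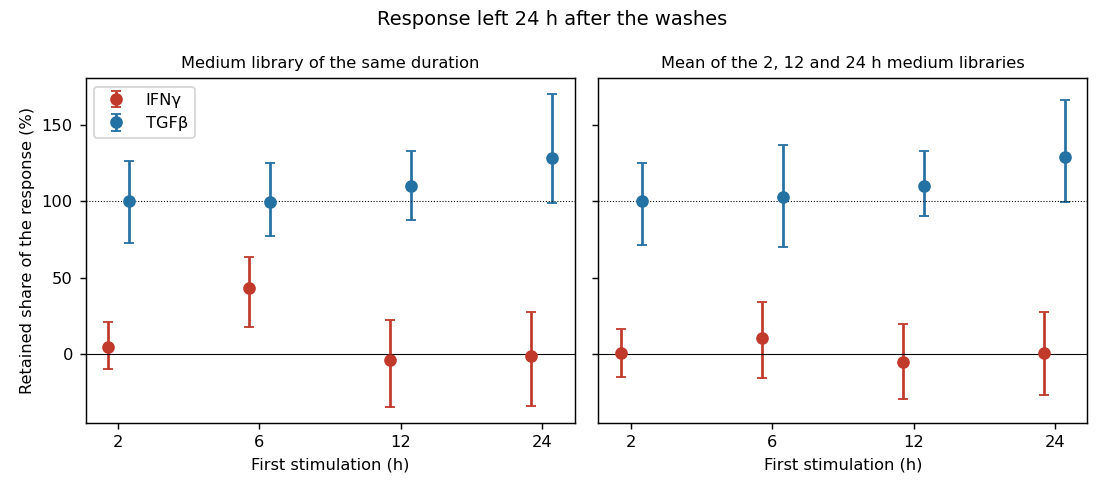
Share of each cytokine's response still present after 24 h in medium (vertical axis, %, median with quartiles over genes) against the duration of the first stimulation (horizontal axis, h), with the medium library of the same duration on the left and the mean of the 2, 12 and 24 h medium libraries on the right as reference. The TGFβ medians lay between 99.4% and 129% and those of IFNγ between -5.11% and 43.1%.

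Both comparisons of a cytokine share the medium libraries, so part of their overlap comes from these. For TGFβ, 2921 genes were called in the same direction with both timings, and 504 would be for independent lists. In 12 simulations of unchanged groups, with the medium libraries redrawn from their fitted mean, 0 were. Few calls can be shared where no gene changes, so this 0 says little about the overlap. The simulations also do not hold the real 6 h medium library. The covariance of the fold changes over genes was 0.296, against 0.0378 on average in the simulations. With the medium libraries split between both comparisons it was 0.21 to 0.244 with 1051 to 1395 shared genes. For IFNγ, 64 genes were shared, 25.8 would be for independent lists, and the simulations gave 0. Its covariance was 0.0917 against 0.0388 on average in the simulations, but its correlation was lower than there, at 0.357 against 0.506. For TGFβ the correlation was 0.874 against 0.492. Split medium libraries gave covariances of -0.0605 to 0.0908 for IFNγ, with 1 to 358 shared genes. The direct contrast of TGFβ first against TGFβ second, added after the data were seen, had 0 genes called by edgeR with 928 at an unadjusted p below 0.05. That of IFNγ first against IFNγ second had 6208. DESeq2 was not run on these contrasts.

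TGFβ before IFNγ was compared with medium before IFNγ to see how cells that had met TGFβ respond to IFNγ. Tnnt2, a cardiac troponin T also found in other cells, lay at 510 ± 25.1 against 52 ± 5.04 CPM (SD, n = 4), higher by 3.30 (SE 0.102, adjusted p = 2.09e-16). Cd274 reached 232 ± 94.2 CPM against 271 ± 16.9 CPM (SD, n = 4; log2 fold change -0.35, adjusted p = 0.575). Cxcl9 reached 91.7 ± 37.2 against 131 ± 17.7 CPM (SD, n = 4; adjusted p = 0.0681), and H2-K1 998 ± 429 against 1443 ± 210 CPM (SD, n = 4; adjusted p = 0.178), none of which passed. With the 6 h medium library left out Cxcl9 passed, at a log2 fold change of -0.62 (adjusted p = 0.0371). H2-K1 was lower at all 4 durations, Cxcl9 at 3 and Cd274 at 2, and the falls were mainly at 12 and 24 h. At 2, 6, 12 and 24 h the log2 differences were 0.11, 0.23, -0.43 and -1.21 for Cd274, and -0.11, 0.05, -0.82 and -1.61 for Cxcl9. The monocyte attractant Ccl2 was lower after TGFβ, with 39.5 ± 30 against 111 ± 29.3 CPM (SD, n = 4; log2 fold change -1.62, adjusted p = 0.000794).

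High changes were those of the protease inhibitor Tfpi2 (4.86), Fbln2 (3.33), Tnnt2 and the decoy receptor Tnfrsf11b (2.99). The lowest were those of the ferritin receptor Scara5 (-2.95), Apod (-2.75), Ly6c1 (-2.45), Slfn4 (-2.19) and the endothelial marker Plvap (-2.13). TGFβ targets rose in 12 and fell in 2 of 22 cases (13 and 2 adjusted over the list alone), with Ctla2a at 4.38 and Vegfa at 1.38 (camera adjusted p = 6.83e-06, and adjusted p = 0.119 with an estimated correlation). MHC class I genes fell in 4 and rose in 0 of 22 cases (4 and 0 adjusted over the list alone), with a median of -0.515 and Tap2 at -0.76 (camera adjusted p = 0.00192, and adjusted p = 0.637 with an estimated correlation). GBP and IRG GTPases fell in 3 and rose in 0 of 17 cases (3 and 0 adjusted over the list alone), with Gbp10 at -1.80 (camera adjusted p = 0.0759). Antiviral genes fell in 1 and rose in 0 of 30 cases (0 and 0 adjusted over the list alone; camera adjusted p = 0.00636, and adjusted p = 0.716 with an estimated correlation). Of that list, 3 fell without the 6 h medium library. Extracellular matrix genes rose in 6 and fell in 4 of 35 cases (6 and 4 adjusted over the list alone; camera adjusted p = 0.797), with the fibronectin gene Fn1 at 1.75 and Col7a1 at 2.04. Of the matrix genes, 6 fell without the 6 h medium library. Cell death genes fell in 6 and rose in 0 of 20 cases (9 and 0 adjusted over the list alone; camera adjusted p = 0.00104, and adjusted p = 0.39 with an estimated correlation), with Tnfsf10, the death ligand TRAIL, at -1.37. The edgeR test with Benjamini-Hochberg adjustment called 2365 genes, 1291 higher and 1074 lower, and 3110 without the 6 h medium library, a fit added after the data were seen. It called 1034 without all 12 h libraries, 1317 without all 24 h libraries and 1233 with no duration factor.

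Whether this effect of TGFβ differed between cells that then received IFNγ and cells that then received medium was tested as an interaction. Of 59 genes called, 48 had a higher effect with IFNγ. The difference is signed, so a higher effect can also be a smaller fall. The effect on Tnnt2 was higher by 1.74 (SE 0.133, adjusted p = 6.98e-08), on the growth factor Fgf2 by 1.54 (SE 0.189), on the arginine-making enzyme Ass1 by 1.51, on Vegfa by 1.13 and on Skil by 0.54 (SE 0.076). IFNγ alone lowered Tnnt2 by a log2 fold change of -1.55 (adjusted p = 7.04e-11), to 52 ± 5.04 CPM from 152 ± 8.53 CPM in medium (SD, n = 4). TGFβ before it gave 510 ± 25.1 CPM against 446 ± 38.9 CPM after TGFβ and medium (SD, n = 4). Megf10 (1.85) and the guidance factor Ntn1 (1.73) had the other highest values. The lowest were Cavin3 (-0.80), Lmo7 (-0.76), Abcb10 (-0.57), Oaf (-0.54) and Itpk1 (-0.54). The GBP and IRG GTPases had a median of 1.71 with 0 of 17 called (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.36e-09, and adjusted p = 0.403 with an estimated correlation). The antiviral genes had a median of 1.38 with 0 of 30 called (0 adjusted over the list alone; camera adjusted p = 3.16e-13, and adjusted p = 0.422 with an estimated correlation). Both lists were lower after TGFβ with either second stimulus, and less so with IFNγ. Without the 6 h medium library the GTPases had medians of -2.46 with medium and -0.553 with IFNγ. For the antiviral genes these were -2.37 and -0.749. Cell cycle genes had a median of -0.318 with 0 of 38 called (0 adjusted over the list alone; camera adjusted p = 7.1e-11, and adjusted p = 0.439 with an estimated correlation).

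The 59 calls by edgeR with Benjamini-Hochberg adjustment were 88 without the 6 h and 201 without the 2 h medium library. They were 34, 36 and 36 without the IFNγ library of 2, 6 and 24 h, 38 and 32 without the TGFβ then IFNγ library of 2 and 12 h. They fell to 31 and 32 without the TGFβ then medium library of 6 and 24 h, and 38, 8 and 17 without all libraries of 2, 12 and 24 h. They were 225 with DESeq2, which held 58 of the 59, 114 with no low-count filter, 16 with no duration factor and 16 in a fit of only these groups.

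IFNγ before TGFβ was compared with medium before TGFβ. The receptor Notch1 was higher after IFNγ, with 28.4 ± 4.81 against 18 ± 2.61 CPM (SD, n = 4), by 0.66 (SE 0.097, adjusted p = 0.00974), as was Arhgap31 by 0.33, a GTPase-activating protein. The secreted glycoprotein Stc2 fell by 0.62 on the log2 scale, and Anxa5, Gnb1, Ndufb8 and Gnas fell by 0.33, 0.31, 0.31 and 0.25, each with an adjusted p of 0.0473. H2-K1 had 627 ± 167 against 328 ± 211 CPM (SD, n = 4), higher at all 4 durations, and did not pass (log2 fold change 1.12, adjusted p = 0.145).

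Of 22 MHC class I genes, 0 were called over all genes by edgeR and 12 rose and 0 fell adjusted over the list alone, with a median of 0.818 (camera adjusted p = 1.29e-12, and adjusted p = 0.32 with an estimated correlation). For H2-K1 the log2 differences at 2, 6, 12 and 24 h were 0.18, 0.72, 1.83 and 1.93. From 2 and 6 h to 12 and 24 h the list fell by a mean of 1.61 on the log2 scale in medium then TGFβ, and by 0.356 in IFNγ then TGFβ, so the difference at the long durations comes largely with lower levels in the sequence compared against. The GBP and IRG GTPases had a median of 0.94 with 0 calls (2 and 0 adjusted over the list alone; camera adjusted p = 3.43e-06, and adjusted p = 0.466 with an estimated correlation). The antiviral genes had a median of 0.491 with 0 calls (0 adjusted over the list alone; camera adjusted p = 0.000624, and adjusted p = 0.657 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation fell in 1 and rose in 0 of 27 cases (5 and 0 adjusted over the list alone; camera adjusted p = 2.61e-05, and adjusted p = 0.215 with an estimated correlation). Of these, 2 fell without the 6 h medium library. Genes of amino acid stress and the unfolded protein response had 0 calls (0 that rose and 9 that fell adjusted over the list alone; camera adjusted p = 6.05e-05, and adjusted p = 0.39 with an estimated correlation). Without the 6 h medium library 5 fell.

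The edgeR test with Benjamini-Hochberg adjustment called 14 genes for IFNγ before TGFβ, 4 higher and 10 lower, with 1726 at an unadjusted p below 0.05. DESeq2 called 160, and edgeR 122 without the 6 h medium library, a fit added after the data were seen. The count was 45, 0, 1 and 5 without the IFNγ then TGFβ library of 2, 6, 12 and 24 h, and 0, 2, 0 and 3 without the medium then TGFβ library of these durations. It was 0 and 0 without all libraries of 6 and 12 h, 93 with no low-count filter, 73 in a fit of only these groups and 1 with no duration factor. The interaction that asks whether the effect of IFNγ first differed between TGFβ and medium as second stimulus had 0 genes called by edgeR, with 1080 at an unadjusted p below 0.05, 0 by DESeq2 and 20 without the 2 h medium library.

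The order of the cytokines was tested by comparing TGFβ then IFNγ with IFNγ then TGFβ. Genes of the IFNγ response were higher where IFNγ came last: Cd274 lay at 232 ± 94.2 against 11.2 ± 5.43 CPM (SD, n = 4), higher by 4.40 (SE 0.439, adjusted p = 1.23e-07). Cxcl9 was higher by 7.41, Apol6 by 6.86, Batf2 by 6.41, Gbp4 by 5.77, Gbp2 by 4.53 and Irf1 by 3.78. H2-K1 (0.58, adjusted p = 0.159) did not pass. The lowest values were those of the collagens Col6a1 (-2.15) and Col3a1 (-1.78), the lectin Cd33 (-1.86), Cpm (-1.78) and the receptor kinase Mertk (-1.74).

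GBP and IRG GTPases were higher in 16 and lower in 0 of 17 cases (17 and 0 adjusted over the list alone; camera adjusted p = 7.6e-09, and adjusted p = 0.39 with an estimated correlation). Chemokines were higher in 8 and lower in 0 of 11 (10 and 0 adjusted over the list alone; camera adjusted p = 3.57e-05, and adjusted p = 0.201 with an estimated correlation). Genes of amino acid stress and the unfolded protein response were higher in 19 and lower in 0 of 26 (20 and 0 adjusted over the list alone), with the transcription factors Atf3 at 2.13 and Atf4 at 0.72 (camera adjusted p = 6.61e-08, and adjusted p = 0.215 with an estimated correlation). Cholesterol synthesis genes were lower in 14 and higher in 0 of 24 cases (14 and 0 adjusted over the list alone), with Insig1 at -0.47 (camera adjusted p = 2.6e-05, and adjusted p = 0.353 with an estimated correlation). Extracellular matrix genes were lower in 18 and higher in 5 of 35 (20 and 5 adjusted over the list alone; camera adjusted p = 0.000508, and adjusted p = 0.397 with an estimated correlation). The fibroblast and endothelium markers were lower in 5 and higher in 0 of 6 cases (5 and 0 adjusted over the list alone), with Dcn at -1.52 (camera adjusted p = 0.00113, and adjusted p = 0.201 with an estimated correlation). Cell cycle genes were higher in 7 and lower in 0 of 38 cases (3 and 0 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.735 with an estimated correlation), and in 20 without the 6 h medium library. The edgeR test with Benjamini-Hochberg adjustment called 4859 genes, 2443 higher and 2416 lower, and 5555 without the 6 h medium library, a fit added after the data were seen. It called 3152 without all 2 h libraries and 3154 without all 12 h libraries.

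**Figure D4:**
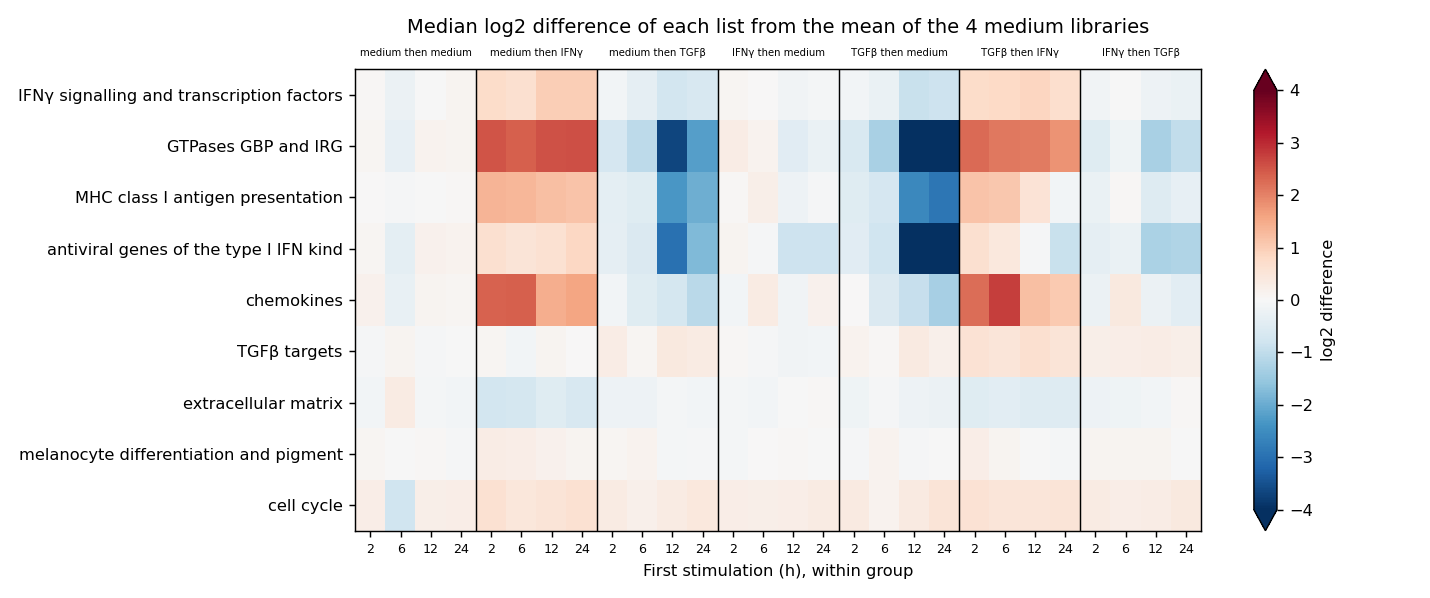
Median log2 difference of 9 gene lists (vertical axis) from the mean of the 4 medium libraries in each library (horizontal axis, by sequence and duration), in colours that saturate at 4 and -4. The GBP and IRG GTPases, MHC class I and antiviral genes were lower at 12 and 24 h than at 2 and 6 h in the sequences with TGFβ, with mean differences of -1.69, -1.27 and -2.04.

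Whether the length of the first stimulation mattered was tested as a trend per doubling of the duration against the trend in the sequence with medium first. After IFNγ and medium, 0 genes had a trend by edgeR with Benjamini-Hochberg adjustment, with 674 at an unadjusted p below 0.05 and 0 by DESeq2. Without the 2 h medium library there were 870, and without all 6 h libraries 2. After TGFβ and medium, 1 gene passed, Gm4841, an interferon-inducible GTPase of which the values were seen before it was chosen. It fell by 2.28 on the log2 scale per doubling (adjusted p = 0.0399), from 5.12 CPM after 2 h to 0.287, 0.115 and 0.0574 CPM after 6, 12 and 24 h, against 319 to 375 CPM with IFNγ as second stimulus. It was also lower at each longer duration in medium then TGFβ, with 0.893, 0.41 and 0.388 CPM at 6, 12 and 24 h, where TGFβ was given for 24 h in every library. DESeq2 called 182 trends there. With the duration in hours there were 145, and with no low-count filter 190. The count was 714, 2, 0 and 0 without the medium library of 2, 6, 12 and 24 h. It was 142, 139, 0 and 0 without the TGFβ library of these durations, and 302, 0 and 0 without all libraries of 6, 12 and 24 h.

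For TGFβ then IFNγ, 0 genes had a trend by edgeR, with 744 at an unadjusted p below 0.05 and 1 by DESeq2. The count was 1 without all 2 h libraries, 41 without all 6 h libraries and 3 without the TGFβ then IFNγ library of 2 h. For IFNγ then TGFβ, 0 genes had a trend by edgeR, with 301 at an unadjusted p below 0.05 and 0 by DESeq2. There were 2 without all 6 h libraries and 1 without the IFNγ then TGFβ library of 6 h.

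The mix of both cytokines was measured in 1 library at 24 h and has no replicate check. Cd274 had 311 CPM in the mix, 284 with IFNγ, 6.26 with TGFβ and 24.5 in medium. H2-K1 had 1455, 1275, 158 and 667 CPM. Mmp12, at 20.8 ± 1.6 CPM with TGFβ alone (SD, n = 4), had 3.59 CPM in the mix. Of 734 genes that responded to a single cytokine, 442 lay within 2-fold of the sum of both log2 differences, or 60.2% (Wilson 95% interval 56.6% to 63.7%, for counting error only). The highest departures from the sum were Ifi209 (4.63), Ly6a (4.6), Rgs1 (4.56), Ifi213 (4.48) and Slfn4 (4.39). The lowest were Ism1 (-3.31), Arrb1 (-3.31), Tenm4 (-2.79), Bnc1 (-2.78) and Aldh1a3 (-2.68). The median difference of the GTPase list from medium was 2.29 in the mix, 2.43 with IFNγ and -2.47 with TGFβ. For the MHC class I list it was 1.14, 1.12 and -2.04.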

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

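Among the tests weighed here, those of depth for the 6 h medium library and of scaling for the lower interferon-type genes were written down before their results were seen, and the others were chosen after.

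The 6 h medium library lay apart from the other medium libraries, with an SD of 0.467 over genes. The other 3, thinned to its total, differed by an SD of at most 0.141, which argues against lower depth. Its nearest sequence was IFNγ then medium at a distance of 0.455, beyond that sequence's own highest distance of 0.221, which argues against a library of another sequence under this label. Cells of another type might add their transcripts, and this stays open: the markers of fibroblasts and endothelium had a median log2 difference of 0.35, under the bound of 0.5 set to exclude it, but that bound was wrong, since the list mixes markers of different cell types that went from 2.38 for Dcn and 1.54 for Col3a1 to -0.741 for Cdh5. The design gives no biological explanation to test for this library.

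In the sequences with TGFβ, antiviral genes were lower after first stimulations of 12 and 24 h than of 2 and 6 h by a mean log2 difference of -2.04, GBP and IRG GTPases by -1.69 and MHC class I genes by -1.27. By sequence the antiviral genes differed by -3.93 in TGFβ then medium, -1.96 in medium then TGFβ, -1.17 in TGFβ then IFNγ and -1.08 in IFNγ then TGFβ, against -0.932 in IFNγ then medium, and the GTPases by -0.34 in TGFβ then IFNγ against -0.546 in IFNγ then medium. Scaling is argued against, with -2.03 by plain library totals and -2.04 by RLE factors. But the mitochondrial share moved with the pattern in 3 of the 4 sequences, and a part of RNA quality or composition was not tested. At 2, 6, 12 and 24 h it was 0.717%, 0.919%, 1.21% and 1.045% in medium then TGFβ. It was 0.927%, 1%, 1.226% and 1.226% in TGFβ then medium, and 0.982%, 0.977%, 1.165% and 1.252% in IFNγ then TGFβ. TGFβ then IFNγ had 0.669%, 0.783%, 0.624% and 0.936%. IFNγ then medium, without TGFβ, had 1.034%, 1.155%, 1.137% and 1.313%. A difference between durations shared by all sequences stays open: without TGFβ the antiviral genes differed by -0.18, but exchanging whole sequences, which keeps the durations paired, gave an exact p = 0.0857 (adjusted p = 0.129 over 3 lists), and the 6 arrangements of the durations taken jointly gave p = 0.333, the smallest they can give. In medium then TGFβ the first stimulation was medium at every duration, so the length of exposure to TGFβ cannot account for that part, and a biological explanation, that longer exposure to TGFβ lowers these genes further, may hold for the part in TGFβ then medium but was not tested apart from culture.

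After the washes and 24 h in medium, the TGFβ response was present and the IFNγ response was largely absent. Shared medium libraries are argued against, since with these split the covariance of the TGFβ fold changes was at least 0.21. The highest simulated value was 0.0417, from simulations that redrew the medium libraries and so do not hold the real 6 h library. The 6 h medium library is argued against, with 3986 genes called after TGFβ without it. Washing that failed alike for both cytokines was to be excluded by a low retained IFNγ response. This response was retained by at most 4.96% after 2, 12 and 24 h. After 6 h it was retained by 10.4% with the other 3 medium libraries as reference, though by 43.1% and 64.7% with the references planned before. These shares cannot decide on the washing, since the amount of each cytokine left and the dose each response needs were not measured. TGFβ left on the cells after the washes cannot be told apart from a lasting response, as the retained medians would come from both. The lowest was 100% against the 2, 12 and 24 h medium libraries and 88.1% with the mean of the other 3 in the denominator. Against the medium library of the same duration it was 99.4%, and 98.3% over genes with an absolute log2 fold change of at least 2. A lasting TGFβ response in NMM cells is therefore a hypothesis that may explain the pattern, with TGFβ left on the cells and washing that failed alike both open.

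Other splits of the 8 libraries of a comparison bear on chance. The real split was the 1 of 35 with as many calls for IFNγ second (6547 genes, highest other split 70) and TGFβ second (3477, highest other 130). The same held for IFNγ first (118, highest other 9) and TGFβ first (4326, highest other 1043). This excludes chance at that share only if the durations do not pair the libraries. Deviations of libraries of 1 duration correlated here by -0.0791 to 0.424, which leaves the pairing open. With pairing, the 7 other splits that part every pair are too few for a share under 5%. IFNγ first called 0 genes without all 12 h libraries and 1 without its 6 h library. In 5 comparisons the deviations correlated by 0.168 to 0.83, and the durations were taken to pair the libraries, though no label says so. With that pairing too, the 7 other splits that part every pair are too few for a share under 5%. The real counts there were 2365 for TGFβ before IFNγ (highest of the 7 other splits 0, of all 5), 14 for IFNγ before TGFβ (0 and 2), 4859 for the order (38 and 2318), 6208 for IFNγ first against second (0 and 0) and 0 for TGFβ first against second (0 and 309), where the splits beyond these 7 keep some durations together. Chance was not excluded for the interaction of TGFβ before IFNγ, with 7 of 100 drawn splits as large. For that of IFNγ before TGFβ the real count was 0, so 100 of 100 were as large whatever the data, which decides nothing. The drawn splits mix libraries of all sequences in an interaction, so the effects of the cytokines enter them. The share for TGFβ before IFNγ and the highest other splits, with 4536 and 849 genes, therefore cannot judge chance for an interaction. Nor was chance excluded for the trend after TGFβ and medium (9 of 35, highest other 2797). Those after IFNγ and medium, TGFβ and IFNγ, and IFNγ and TGFβ had 0 real calls. For them 35 of 35 splits were as large whatever the data, with highest others of 830, 545 and 1 genes. Splits of a trend mix libraries of both sequences, so a difference between the sequences enters the slopes. The highest splits of 545 to 2797 genes for 3 of these trends cannot be told apart from that. The highest split of 309 genes for TGFβ first against second points to a structure of the samples, and its cause was not tested.

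A library far from the other 3 of its sequence was found in 15 of 154 groups of 4 values by Dixon's ratio at a level of 5%, and chance flags about 1 in 20 groups. Not all of the 15 are reported here. In the 6 h medium library the mitochondrial share was 1.24% against 0.841% to 0.868%. There Gbp2 had 97.9 CPM against 211 to 233, Tap1 90.4 against 136 to 146, Tgfbr1 166 against 104 to 108, Tgfbr2 85.1 against 56.3 to 58.9 and Ifngr1 15.7 against 13.7 to 13.9. With IFNγ as second stimulus, the 2 h library had 42.9 CPM of Smad7 against 37.3 to 38.1 and 342.5 of Tap1 against 338.3 to 338.9. With TGFβ as second stimulus, the 12 h library had 51.4 CPM of Tgfbr2 against 52 to 52.1. After IFNγ and medium, Ciita had 0.105 CPM at 2 h against 0, and Ifngr1 14.9 at 24 h against 13.2 to 13.5. After TGFβ and medium, Mitf had 10.3 CPM at 24 h against 12.8 to 12.9, and Socs1 5.17 at 2 h against 3.54 to 3.67. After IFNγ and TGFβ, Ifngr1 had 13.7 CPM at 6 h against 13.4.

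The effect of TGFβ first differed between IFNγ and medium as second stimulus in 59 genes by the interaction test. Among those named, the difference was 1.85 for Megf10, 1.74 for Tnnt2, 1.73 for Ntn1, 1.54 for Fgf2, 1.51 for Ass1 and 0.54 for Skil, and -0.80 for Cavin3, -0.76 for Lmo7, -0.57 for Abcb10, -0.54 for Oaf and -0.54 for Itpk1. The trend of Gm4841 with the duration of TGFβ differed from that in medium by -2.28 on the log2 scale per doubling, and this gene was also lower at each longer duration in medium then TGFβ, down to 0.388 CPM at 24 h, where exposure to TGFβ was 24 h throughout.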

How the results depend on the processing

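The list tests without the 6 h medium library, the retained share against the 2, 12 and 24 h medium libraries, the counts of TGFβ before IFNγ, IFNγ before TGFβ and the order without the 6 h medium library, and the tests of TGFβ or IFNγ first against second were chosen after the data were seen, and the other settings before. With RLE factors and with library sizes that leave out mitochondrially encoded genes, all counts of called genes stayed within 1.5 times. Over 1000 results of named genes and 19696 values under the alternatives, 18484 stayed on their side of the threshold, 990 lost the call and 222 gained it. Direction was compared only where the main or the alternative fit called the gene, and 0 of those reversed. Depth limits genes near the floor such as Ciita.

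Leaving out 1 library or 1 duration at a time, the counts ranged from 5468 to 6374 for IFNγ second, 1848 to 3720 for TGFβ second, 0 to 498 for IFNγ first, 2690 to 4378 for TGFβ first, 1034 to 3110 for TGFβ before IFNγ, 0 to 122 for IFNγ before TGFβ and 3152 to 5555 for the order. The highest of these last 3 came without the 6 h medium library, and among the libraries compared they were 2251, 45 and 5021. The interactions ranged from 8 to 201 for TGFβ before IFNγ and 0 to 20 for IFNγ before TGFβ. The trends ranged from 0 to 870 after IFNγ and medium, 0 to 714 after TGFβ and medium, 0 to 41 for TGFβ then IFNγ and 0 to 2 for IFNγ then TGFβ. These fits rest on fewer libraries.

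Within these ranges, TGFβ second called 2189 genes and TGFβ before IFNγ 1317 without all 24 h libraries, and the order 3154 without all 12 h libraries. IFNγ first called 43 without all 24 h libraries, 9 and 41 without its 12 and 24 h libraries, and 64 and 23 without the 6 and 12 h medium libraries. IFNγ before TGFβ called 1, 5, 2 and 3 without the IFNγ then TGFβ library of 12 and 24 h and the medium then TGFβ library of 6 and 24 h. The interaction of TGFβ before IFNγ called 38 and 17 without all 2 and all 24 h libraries, and 34, 36 and 36 without the medium then IFNγ library of 2, 6 and 24 h. It called 38 and 32 without the TGFβ then IFNγ library of 2 and 12 h, and 31 and 32 without the TGFβ then medium library of 6 and 24 h. The trend after TGFβ and medium called 302 without all 6 h libraries, and 142 and 139 without its 2 and 6 h libraries. For these, the cause was not tested.

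With no replicate block, that is without the duration factor, TGFβ second called 1727 genes, IFNγ first 6, TGFβ first 2615, TGFβ before IFNγ 1233, IFNγ before TGFβ 1 and the interaction of TGFβ before IFNγ 16, while IFNγ second and the order stayed within 1.5 times. In a fit of only the libraries compared, which has fewer samples, TGFβ second called 1047 genes, IFNγ first 0, TGFβ first 1381, IFNγ before TGFβ 73 and the interaction of TGFβ before IFNγ 16. DESeq2 called 403 genes for IFNγ first, 160 for IFNγ before TGFβ, 225 for that interaction, 182 for the trend after TGFβ and medium and 1 for that of TGFβ then IFNγ, and the cause was not tested. With no low-count filter the counts were 93 for IFNγ before TGFβ, 114 for that interaction, 190 for the trend after TGFβ and medium, 1 for TGFβ then IFNγ and 1 for IFNγ then TGFβ. With the duration in hours 145 genes had a trend after TGFβ and medium. For the filter and the scale of duration too, the cause was not tested.

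Of 161 list tests, 78 passed by camera with the preset correlation, 0 with an estimated correlation, which widens the null for lists whose genes move together, and 73 by fry. Without the 6 h medium library 77 passed, 73 of them the same tests. The retained share of IFNγ after 6 h was 10.4% against the 2, 12 and 24 h medium libraries, against 43.1% with the 6 h medium library. With the mean of the other 3 medium libraries in the denominator, a setting planned before, it was 64.7% (quartiles 17.9% and 126%), and that of TGFβ was 88.1% after 2 h, 126% after 6 h and 110% after 24 h. With group means in place of the 24 h libraries, 73.8% of the genes of the mix lay within 2-fold of the sum. With the medium libraries split, the overlap of first and second stimulus was 21, 154, 358 and 1 genes for IFNγ and 1395, 1369, 1051 and 1377 for TGFβ, in fits with fewer libraries per comparison.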

Other observations

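The values given here come from tests fixed beforehand, apart from list and gene results without the 6 h medium library, and no hypothesis is added.

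Some genes went in opposite directions with the 2 cytokines as second stimulus, and those given here were chosen after their values were seen, with no test over a list. The fibronectin gene Fn1 had 7101 ± 2130 CPM in medium, 2778 ± 424 with IFNγ and 11670 ± 2280 with TGFβ (SD, n = 4; adjusted p = 3.65e-06 and 0.00923 by edgeR). It had 9483 ± 3400 CPM with TGFβ then IFNγ (SD, n = 4) and 5914 CPM in the mix. Col7a1, the collagen of anchoring fibrils, had 137 ± 22.5, 68.1 ± 9.86 and 288 ± 48.3 CPM in medium, with IFNγ and with TGFβ (SD, n = 4; adjusted p = 1.8e-05 and 4.08e-05 by edgeR), and 237 CPM in the mix. The growth factor Fgf2 had 28.7 ± 11.1, 8.87 ± 0.88 and 44.7 ± 0.911 CPM (SD, n = 4; adjusted p = 5.58e-09 and 0.000551 by edgeR), and 35.7 CPM in the mix. For these 3 genes the calls with both cytokines held without the 6 h medium library. Mmp12 had 2.21 ± 1.72 CPM in medium, 0.715 ± 0.349 with IFNγ and 20.8 ± 1.6 with TGFβ (SD, n = 4; adjusted p = 0.0106 and 2.34e-07 by edgeR), and its fall with IFNγ did not pass without the 6 h medium library (adjusted p = 0.131). It had 8.75 ± 2.96 CPM with TGFβ then IFNγ and 25.5 ± 10.7 CPM with IFNγ then TGFβ (SD, n = 4). Ly6a went the other way, with 22.1 ± 2.28 CPM in medium, 127 ± 14.2 with IFNγ, 3.21 ± 3.33 with TGFβ and 43.1 ± 26.1 with TGFβ then IFNγ (SD, n = 4). The receptor Notch1 had 23.9 ± 2.08 CPM in medium, 57.1 ± 0.76 with IFNγ and 18 ± 2.61 with TGFβ (SD, n = 4).

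Genes of undifferentiated and neural crest melanoma rose with IFNγ as second stimulus in 10 and fell in 2 of 17 cases (10 and 3 adjusted over the list alone), with the transcription factor Jun at 1.37 and the intermediate filament Nes at 1.22 (camera adjusted p = 0.0225, and adjusted p = 0.39 with an estimated correlation). With TGFβ they rose in 4 and fell in 2 (6 and 3 adjusted over the list alone), with Nt5e at 1.22 and Sox9 at 0.63, a median of 0.0728, a mean of -0.132 and no call as a list (camera adjusted p = 0.283), and 1 fell without the 6 h medium library. T cell inhibitory ligands and enzymes rose with IFNγ in 7 and fell in 2 of 13 cases (7 and 2 adjusted over the list alone), with Tnfrsf14 at 3.39 and Cd276 at -0.90 (camera adjusted p = 0.0988). The 8 melanocyte genes rose in 4 and fell in 1 case with IFNγ (4 and 1 adjusted over the list alone; camera adjusted p = 0.203), with a median of 0.209 and a mean of -0.00215. Genes of MAPK output rose in 10 and fell in 5 of 18 cases (10 and 5 adjusted over the list alone; camera adjusted p = 0.183), with Fosl1 at 0.98 and the feedback inhibitor Spry1 at -1.98. TGFβ signalling genes rose in 4 and fell in 10 of 21 (4 and 11 adjusted over the list alone; camera adjusted p = 0.0523), and genes of epithelial-mesenchymal transition rose in 7 and fell in 4 of 22 (7 and 4 adjusted over the list alone; camera adjusted p = 0.346).

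Glycolysis and hypoxia genes rose in 16 and fell in 2 of 28 cases with IFNγ (17 and 2 adjusted over the list alone), with the hexokinase Hk2 at 0.97 (camera adjusted p = 0.00222, and adjusted p = 0.504 with an estimated correlation). With TGFβ they rose in 11 and fell in 0 (11 and 0 adjusted over the list alone), with Ndrg1 at 1.04 (camera adjusted p = 0.000391, and adjusted p = 0.466 with an estimated correlation). Genes of amino acid stress and the unfolded protein response rose in 16 and fell in 2 of 26 cases with IFNγ (16 and 2 adjusted over the list alone), with Atf3 at 1.69 (camera adjusted p = 0.00271, and adjusted p = 0.477 with an estimated correlation), and 10 rose without the 6 h medium library. Cholesterol synthesis genes rose in 5 and fell in 6 of 24 with IFNγ (5 and 6 adjusted over the list alone; camera adjusted p = 0.432) and rose in 7 and fell in 0 with TGFβ (10 and 0 adjusted over the list alone), with Insig1 at 0.35 (camera adjusted p = 0.00142, and adjusted p = 0.457 with an estimated correlation). Genes of oxidative phosphorylation fell in 12 and rose in 3 of 27 with IFNγ (12 and 3 adjusted over the list alone; camera adjusted p = 0.0337, and adjusted p = 0.507 with an estimated correlation). The share of mitochondrially encoded transcripts differed between these groups too, at 0.676% to 0.814% with IFNγ as second stimulus against 0.841% to 1.24% in medium, and at 1.03% to 1.31% after IFNγ and medium. p53 targets rose in 7 and fell in 5 of 20 with IFNγ (7 and 5 adjusted over the list alone; camera adjusted p = 0.797), with a median of -0.0477 and a mean of 0.124.

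The 16 reference genes rose in 3 and fell in 3 cases with IFNγ (3 and 3 adjusted over the list alone; camera adjusted p = 0.786) and rose in 5 and fell in 1 with TGFβ (7 and 1 adjusted over the list alone), with a median of 0.146 (camera adjusted p = 0.00408, and adjusted p = 0.25 with an estimated correlation). Without the 6 h medium library they still passed with TGFβ (camera adjusted p = 0.00608), with a median of 0.108. There the medians with TGFβ were 0.0984 for cell cycle, 0.191 for glycolysis and hypoxia and 0.203 for cholesterol synthesis genes. A camera call with TGFβ at so small a median therefore does not set a list apart from the reference genes.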
